A study of Mus musculus with 18 samples.

How the data were processed

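Total RNA from mouse embryonic stem cells was measured on BeadChips of the Sentrix Mouse-6 design, version 1.1 (Illumina), on which each probe is read from many beads. The series holds 18 arrays in 9 groups of 2. CGR8 cells were sampled at days 0, 1 and 3 of withdrawal of leukaemia inhibitory factor (LIF), and at the same days in the presence of cyclosporin A (CsA), a calcineurin inhibitor. CGR8 cells carrying an inducible deltaCnA, a form of calcineurin A that is active without its usual regulation, were sampled at days 0, 1 and 4 of tetracycline (Tc) withdrawal, which induces it. Groups and replicate numbers were taken from the sample titles.

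The probe intensities were deposited by the authors on a linear scale and not normalized between arrays, per the file headers. Between 31.15% and 35.24% of the values on an array lay below 0, so a background had been subtracted before deposit, although no source used here states it. Each intensity comes with a detection p-value deposited by the authors, which ranks the probe among negative controls. RNA was extracted with Trizol and biotinylated cRNA was made with an Ambion MessageAmp kit, per the labels' protocols. The scanner software and the normalization of the series matrix are not given in the sources used here. The values of that matrix were deposited on a linear scale too. They ranked the probes of each array exactly as the intensities did, and every array had a median near 10.9. The values of the day 0 array of LIF withdrawal, replicate 1, were identical in both tables.

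Array quality was even. Mean intensity per array ran from 286.9 to 484, and 40.43% to 44.07% of the 46632 probes were detected at a p-value under 0.05. The number of arrays, and the background for dim probes, limit the precision. The most negative intensities were lower on the deltaCnA arrays (-57.95 to -47.00) than on the others (-29.37 to -23.71). Replicates correlated at r = 0.9922 to 0.9957 across genes, which are not independent of each other, and no replicates held identical values.

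From these values, the background was modelled with the normexp method of limma 3.58.1 in R 4.3.3, using the detection p-values to find the negative controls and an offset of 16, and arrays were quantile normalized and taken to log2. Of the 46632 probes, 29976 had 1 gene symbol in the platform annotation, 10 had several and 16646 had none. Entrez identifiers matched 29921 probes to a current RefSeq gene table, and 0 symbols changed. Probes detected on both arrays of at least 1 group were kept, 21691 in all, of which 5642 had no gene name. The brightest kept probe stood for its gene, which gave 10980 genes. Among the 3624 genes with 2 or more kept probes, probes can disagree: of 1490 such genes called at day 3 of LIF withdrawal, another probe was called the same way for 833 and the opposite way for 23.

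Each comparison was a contrast in a single linear model of the 9 group means over all 18 arrays, with 9 residual degrees of freedom, fitted with limma (lmFit, and eBayes with an intensity trend). P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene counts as called, risen, fallen or changed at an adjusted p under 0.05. Errors given with a log2 change are standard errors of the change. The comparisons were each later day against day 0 within each series, CsA against no CsA at each day, and the CsA by day interaction, which asks whether the change from day 0 differs with CsA. Where the dimmer group was undetected on 1 or both of its arrays, a fold is given as "at least", computed from the bright group's mean against the lowest detected level of the dim group's arrays, or the probe's own level where that was higher. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

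The following were chosen before the data were examined: the comparisons, the model, the rule for named genes, the alternatives other than those named as added, and 22 gene lists. The lists cover core pluripotency, naive pluripotency, LIF-STAT3 targets, primed epiblast, mesendoderm and primitive streak, primitive endoderm, trophectoderm, mesoderm, neuroectoderm, mesenchymal and EMT genes, epithelial genes, fibroblast, blood and endothelium, calcineurin-NFAT components, Src family and ERK feedback, cell cycle, p53 targets, ER stress and integrated stress response, cholesterol synthesis, hypoxia and glycolysis, 2-cell-like genes, and imprinted genes. List members that passed no probe filter or have no probe are not analysed here. Lists were tested with camera, a competitive test of a list against all other genes, at a preset inter-gene correlation of 0.01, and p-values were adjusted over all 242 tests (22 lists in 11 comparisons). Camera was also run with the correlation estimated from the data. Of 52 list shifts called at the preset value, 9 were called with an estimated correlation. Some lists overlap: naive pluripotency and LIF-STAT3 targets share 3 genes.

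Named genes are the 6 higher and 6 lower genes with the largest changes for LIF withdrawal at day 3, CsA at day 3 and deltaCnA at day 4. For the other comparisons they are 3 of each. These genes had to be called, to have both arrays of a group above both of the other group (not asked of interactions), and to be detected in the brighter group. Up to 4 called members of each list also count as named (or 2 members, as values, where none was called), although only some of them are printed below. A gene not printed for a comparison may thus have been called. Ppp3ca, Ppp3cb, Rcan1 and Src are named throughout. Gene models without a proper name were counted but not named.

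Alternatives were no background correction, median scaling, the series matrix, no detection filter, the mean of a gene's probes, only the arrays compared, the replicate number as a block, and leaving out each array. The BeadChip as a block was not run, because the files used here name no chip. Overlaps between comparisons that share day 0 arrays were set beside 20 simulations of unchanged groups. The steps were tested on simulated data before use. For LIF withdrawal at day 3 over 10980 genes, the first draw recovered 20.9% of 67 genes changed by 0.5 on the log2 scale, 83.58% of 67 changed by 1 and 100% of 66 changed by 2. Over 20 further draws these shares ran from 17.9% to 38.8%, 74.6% to 92.5% and 98.5% to 100%. Of 148 genes called in the first draw, 136 were among these changed genes, 7 were members of a list moved by 0.5 and 5 were unchanged, and the further draws called 2 to 13 unchanged genes. The data gave 4192 calls in that comparison, far more than the simulations, and a larger share of changed genes eases the adjustment. Recovery in the data may therefore be higher. The simulated errors were independent between genes, so the unchanged calls take no account of correlated genes.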

Results

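The arrays followed mouse embryonic stem cells of the CGR8 line, which LIF keeps undifferentiated, through LIF withdrawal with and without CsA, and through induction of deltaCnA. The question the series names is which genes calcineurin and its NFAT transcription factors regulate. CsA blocks calcineurin and deltaCnA supplies its activity. Each of the 9 groups holds 2 arrays, so every group mean below has n = 2. The first 3 principal components over 10980 genes held 37.97%, 20.14% and 14.08% of the variance.

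After 1 day without LIF, the genes nearest to LIF signalling fell and epiblast genes rose. Socs3, the feedback inhibitor that STAT3 induces, fell 27.9-fold (log2 change -4.80 ± 0.20, SE), and Bcl3, another STAT3 target, fell at least 6.78-fold. Fgf5, a marker of the primed epiblast, was at least 10.7-fold higher, Pou3f1 (Oct6) rose 11.1-fold, and Slc40a1, the iron exporter ferroportin, rose 7.73-fold. Serping1, a complement inhibitor, fell at least 6.25-fold, to a level detected on 1 of 2 arrays. In all, 924 of 10980 genes changed, 409 up and 515 down, with 89 up and 138 down by at least 2-fold.

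Of 18 measured LIF-STAT3 targets, 12 fell and 6 were not called at day 1 (adjusted p = 2.43e-21), among them Junb (-1.90 ± 0.21) and Klf4 (-1.89 ± 0.17). Of 18 naive pluripotency genes, 13 fell (adjusted p = 2.81e-13), including Tfcp2l1 (-1.63 ± 0.12) and Tbx3 (-1.39 ± 0.17), and 14 fell when adjusted over the list alone. Of 12 primed epiblast genes, 10 rose (adjusted p = 1.88e-13), including Sall2 (2.71 ± 0.25). These 3 shifts were also called with an estimated correlation (adjusted p = 0.0118, 0.0488 and 0.0488). Imprinted genes shifted up, with 3 of 12 risen (Cdkn1c 1.13 ± 0.13, Snrpn 0.82 ± 0.11 and Peg3 0.80 ± 0.12; adjusted p = 0.0179), but adjusted p = 0.154 with an estimated correlation. That shift was also lost with the mean of a gene's probes (0.0710) and without replicate 2 of day 0 (0.0728) or of day 1 (0.0537). Core pluripotency genes did not shift as a list (adjusted p = 0.544), although Nanog fell (-0.77 ± 0.11). Ppp3ca (0.27 ± 0.16), Ppp3cb (0.10 ± 0.13), Rcan1 (-0.32 ± 0.13) and Src (0.20 ± 0.20) were not called. Without replicate 1 of day 1 the count of changed genes was 476, and without replicate 2 of day 0 it was 574.

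By day 3 without LIF, 4192 genes had changed, 2020 up and 2172 down, and 710 and 629 of them by at least 2-fold. The largest rises were in Acta2, smooth muscle actin (at least 63.6-fold), Fgf5 (at least 39.1-fold), the immunoproteasome subunit Psmb8 (at least 37.2-fold), the carbonic anhydrase Car4 (at least 27.7-fold), the guanylate-binding protein Gbp2b (at least 20.3-fold) and Acta1, skeletal actin (at least 16.7-fold). The largest falls were in the small GTPase Mras (at least 29.2-fold), Spink1 (25.4-fold), Khdc3, a gene of the oocyte and early embryo (21.5-fold), and Myo1f (20.5-fold). Acta2, Psmb8 and Mras were detected on 1 of 2 arrays of their dimmer group. Fbxw5 (at least 15.7-fold lower, detected on 1 of 2 arrays at day 3) also ranks here, but its probe read brightly on some arrays and not on others within a group, and its call ended without replicate 1 of day 3 (adjusted p = 0.0723). Spats1 fell at least 9.27-fold.

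All 18 naive pluripotency genes had fallen by day 3 (adjusted p = 8.59e-18, and adjusted p = 0.0392 with an estimated correlation). Klf4 fell 12.5-fold, Tbx3 12.2-fold, Tcl1 6.91-fold and the DNA demethylase Tet2 6.48-fold. LIF-STAT3 targets remained shifted down, with 11 fallen and 1 risen of 18 (adjusted p = 2.92e-05, but adjusted p = 0.110 with an estimated correlation). Socs3 (-3.43 ± 0.20) and Bcl3 (-2.30 ± 0.17) had fallen. Of 13 core pluripotency genes, 4 fell and 1 rose, with no shift as a list (adjusted p = 0.388). Nanog (-1.44 ± 0.11), Dppa2 (-1.13 ± 0.19) and Trim28 (-0.59 ± 0.10) fell, and Lin28a rose (0.49 ± 0.12).

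Genes of other cell states were unevenly affected at day 3. Of 12 primed epiblast genes, 10 rose, with Pou3f1 up 26.0-fold and Sall2 up 16.5-fold (adjusted p = 2.61e-07, but adjusted p = 0.114 with an estimated correlation). Epithelial genes rose, 10 of 13 with 1 lower, led by the tight junction genes Cldn7 (at least 9.14-fold) and Cldn3 (3.96-fold) and the keratin Krt18 (7.78-fold) (adjusted p = 2.81e-06, but adjusted p = 0.0532 with an estimated correlation). Imprinted genes rose, 8 of 12 with 1 lower, including Cdkn1c (3.22-fold), Igf2 (3.21-fold), Peg3 (3.04-fold) and Dlk1 (2.74-fold) (adjusted p = 0.000335, but adjusted p = 0.0628 with an estimated correlation). Other lineage lists moved both ways without a called shift. Among mesendoderm and primitive streak genes, 3 rose, led by Fgf8 (at least 16.6-fold), and 2 fell (adjusted p = 0.388). Among mesoderm genes, 3 rose and 4 fell, including Bmp4 (-2.27 ± 0.23) and Meox1 (at least 2.15-fold lower) (adjusted p = 0.835). Among trophectoderm genes, 5 rose and 2 fell (adjusted p = 0.138), and Krt8 and Krt18 are on that list and the epithelial one. Among neuroectoderm genes, 4 of 7 rose, with Pax6 (2.35 ± 0.22) and Nes (at least 2.76-fold), and Ncam1 fell (adjusted p = 0.107).

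Among 17 mesenchymal and EMT genes, 6 rose, including Tagln (at least 4.26-fold), and 4 fell, including Zeb1 (at least 6.36-fold) (adjusted p = 0.570). The remaining lists did not shift at day 3: primitive endoderm (adjusted p = 0.486), fibroblast (0.198), blood and endothelium (0.488), calcineurin-NFAT components (0.503), Src family and ERK feedback (0.998), cell cycle (0.331), p53 targets (0.0558), ER stress (0.345), cholesterol synthesis (0.349), hypoxia and glycolysis (0.729) and 2-cell-like genes (0.719). Single members still changed. Dcn, a fibroblast gene, rose at least 5.70-fold, Dab2 of the primitive endoderm list rose 7.06-fold, Tal1 of the blood list rose 3.22-fold and Nfatc4 rose 2.60-fold. Ppp3ca (-0.14 ± 0.16), Ppp3cb (0.18 ± 0.13), Rcan1 (-0.16 ± 0.13) and Src (0.10 ± 0.20) were not called. The Rcan1 value is from its brightest probe. Of 2 dimmer Rcan1 probes, examined after the results were seen, 1 was not called (-0.02 ± 0.18) and the other rose by at least 1.02 on the log2 scale (adjusted p = 0.000402 over probes, detected on 1 of 2 arrays at day 0). With CsA that second probe was not called at day 3 (0.08 ± 0.21).

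**Figure D1:**
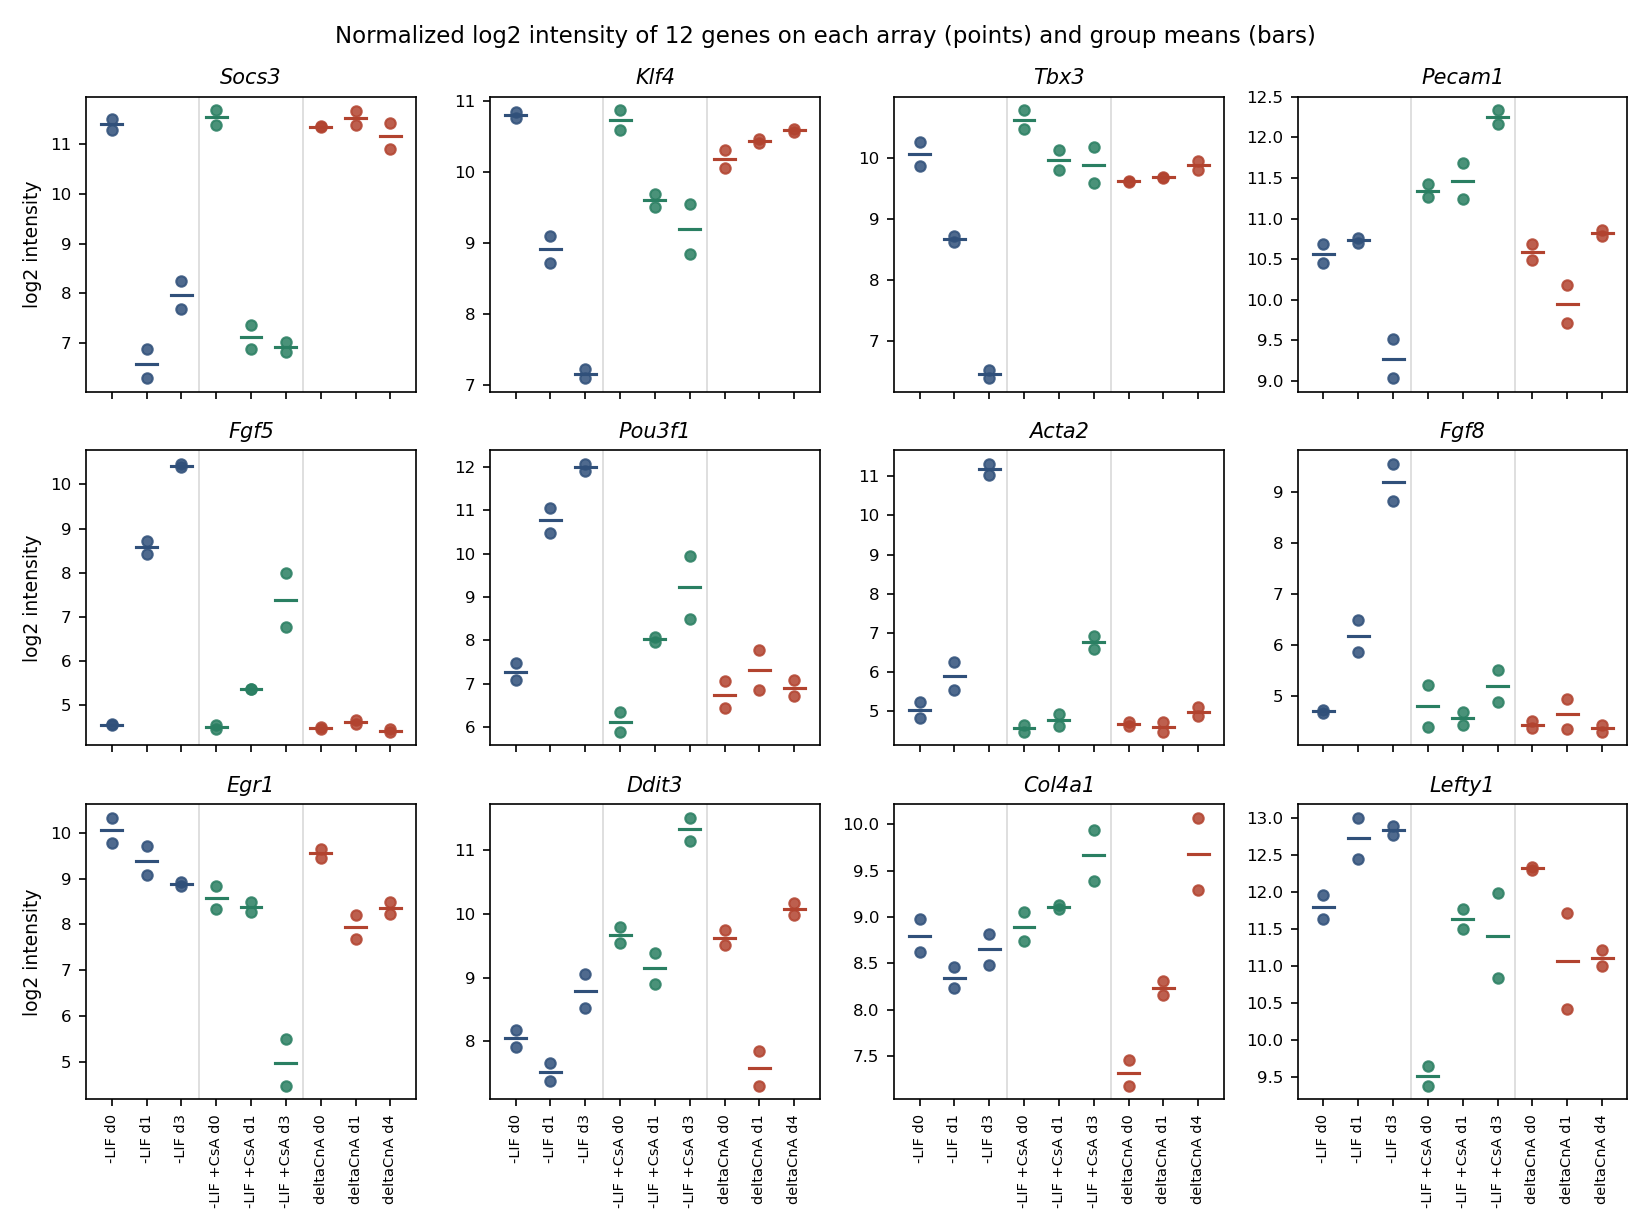
Normalized log2 intensity (vertical axes) of 12 genes in the 9 groups (horizontal axes). Points are single arrays and bars means of 2 arrays (blue LIF withdrawal, green LIF withdrawal with CsA, red deltaCnA induction), and at day 3 Tbx3 and Pecam1 are higher with CsA by 3.42 and 2.99.

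With CsA present, LIF withdrawal still lowered the STAT3 targets but moved the naive genes less. At day 1 the STAT3 targets too moved less, with a mean change of -0.86 with CsA and -1.24 without. At day 1, Socs3 fell 21.2-fold and Bcl3 at least 6.69-fold (detected on 1 of 2 arrays at day 1), the mucin Muc1 fell at least 5.06-fold, and the cyclin gene Ccno (7.29-fold) and Slc40a1 (5.68-fold) rose. LIF-STAT3 targets fell, 12 of 18 (adjusted p = 8.59e-18, and 0.0131 with an estimated correlation), and primed epiblast genes rose, 8 of 12 (adjusted p = 6.25e-13, and 0.0488 with an estimated correlation). Of 18 naive genes, 6 fell (adjusted p = 0.000223, but adjusted p = 0.226 with an estimated correlation). In all, 498 genes changed, 257 up and 241 down. The count fell to 236 and 294 without replicates 1 and 2 of day 0, and to 258 and 246 without those of day 1. All 346 genes called at day 1 in both courses, which share no arrays, moved the same way, against 20.9 expected of independent lists. Not called at day 1 with CsA were Ppp3ca (0.15 ± 0.16), Ppp3cb (0.23 ± 0.13), Rcan1 (-0.31 ± 0.13) and Src (0.05 ± 0.20).

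At day 3 with CsA, 3246 genes had changed, 1639 up and 1607 down. Pdzk1 (14.9-fold) and Car4 (at least 9.89-fold) rose most, and Socs3 (24.3-fold), Spink1 (-4.25 ± 0.22) and the immediate early gene Egr1 (at least 9.59-fold, detected on 1 of 2 arrays at day 3) fell most. Psmc1 (higher by at least 3.28 on the log2 scale) also ranks among the rises, with a probe that read on some arrays of a group and not others. Of the LIF-STAT3 targets, 12 fell and 2 rose (adjusted p = 1.60e-08, and 0.0488 with an estimated correlation), among them Bcl3 (at least 7.54-fold lower), Gbx2 (-2.51 ± 0.17) and Ier3 (-2.27 ± 0.23). Of the naive genes, 11 fell, led by Klf4 (-1.54 ± 0.17), and Pecam1 rose (0.91 ± 0.16) (adjusted p = 0.000223, but adjusted p = 0.226 with an estimated correlation). Primed epiblast genes rose, 8 of 12, including Pou3f1 (3.11 ± 0.33) and Fgf5 (at least 4.63-fold) (adjusted p = 3.58e-06, but adjusted p = 0.146 with an estimated correlation). Epithelial genes rose, 9 of 13 (adjusted p = 0.000572, but adjusted p = 0.114 with an estimated correlation). Imprinted genes rose in 5 cases and fell in 1 (adjusted p = 0.0179, but adjusted p = 0.154 with an estimated correlation).

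The lists of Src family and ERK feedback genes and of p53 targets were also called at day 3 with CsA. Of 15 Src family and ERK feedback genes, 6 fell and 1 rose, including Etv4 (-2.89 ± 0.21) and the feedback inhibitor Spry4 (-2.66 ± 0.27) (adjusted p = 0.0133, but adjusted p = 0.469 with an estimated correlation). Of 13 p53 targets, 7 rose, with Trp53inp1 (0.99 ± 0.16) and Mdm2 (0.68 ± 0.12) (adjusted p = 0.0135, but adjusted p = 0.346 with an estimated correlation). The p53 targets had changed by a mean of 0.40 with CsA and 0.39 without, with no interaction (adjusted p = 0.980). Ppp3ca (0.52 ± 0.16) and Ppp3cb (0.53 ± 0.13) rose at day 3 with CsA, the former not without replicate 2 of day 0 (adjusted p = 0.168) or replicate 1 of day 3 (0.165), and Rcan1 (-0.01 ± 0.13) and Src (0.22 ± 0.20) were not called. Without replicate 2 of day 0 with CsA the count of changed genes was 2032, and without replicate 1 of day 3 it was 2105.

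**Figure D2:**
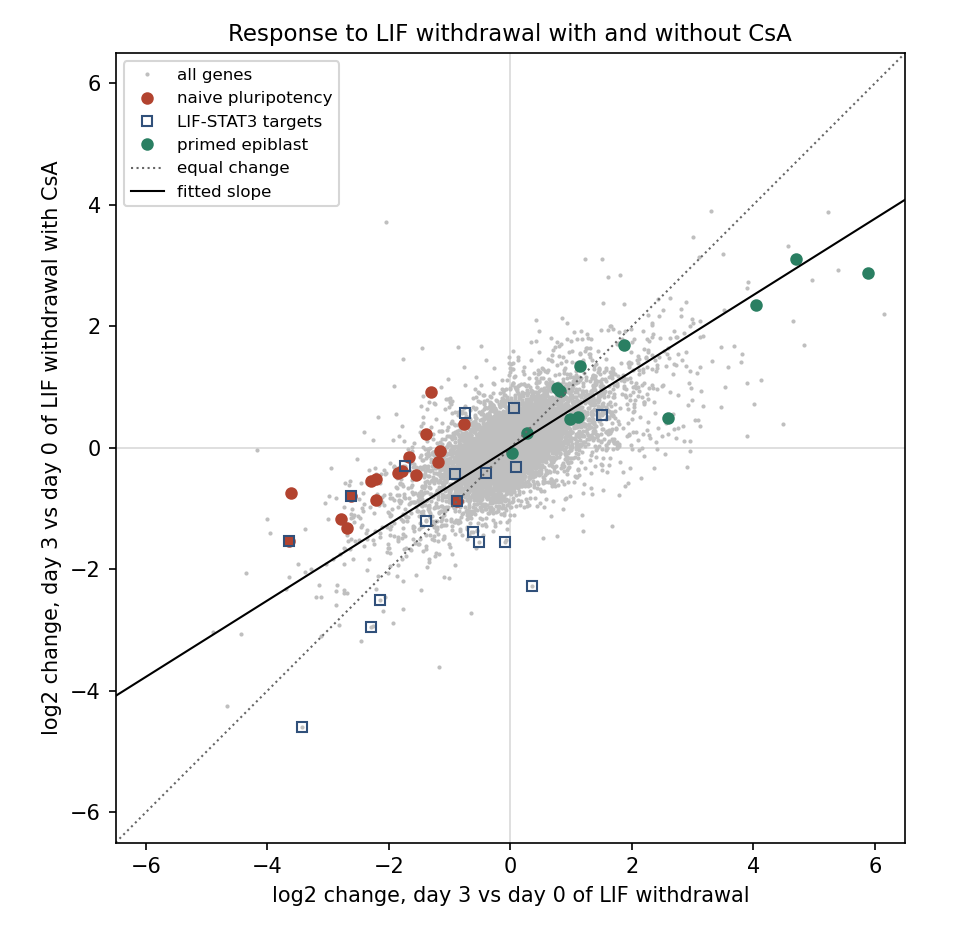
Log2 change from day 0 to day 3 of LIF withdrawal without CsA (horizontal axis) and with CsA (vertical axis), 1 point per gene. The fitted line has a slope of 0.63; naive pluripotency genes other than Klf5 lie above it on the left, nearer to no change with CsA, and LIF-STAT3 targets lie on both sides of the dotted line of equal change.

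CsA was next set against no CsA at each day. At day 0 the CsA arrays already differed, with 1446 genes called, 678 higher and 768 lower, and 56 and 59 of them by at least 2-fold. The labels do not say whether, or how long, the day 0 cells had received CsA. Genes of the endoplasmic reticulum stress response were higher: of 17 on the list, 8 were higher and 0 lower, including Ddit3 (CHOP, 3.08-fold), Sdf2l1 (2.58-fold), the disulphide isomerase Pdia4 (2.17-fold) and Xbp1 (2.15-fold) (adjusted p = 1.11e-08, but adjusted p = 0.0796 with an estimated correlation), and 10 were higher when adjusted over the list alone. Cox6a2, a muscle form of a cytochrome oxidase subunit (at least 3.73-fold), the secretory cell factor Bhlha15 (3.65-fold) and Snhg11 (3.26-fold) were also higher. The Nodal target Lefty1 (4.84-fold) and Ccno (4.49-fold) were lower, as was Fbxw5, whose call ended without replicate 2 of the arrays without CsA (adjusted p = 0.0809) or replicate 1 of the CsA arrays (0.0937).

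Primed epiblast genes were lower with CsA at day 0, 5 of 12, such as Lef1 (at least 1.95-fold) and Fgf15 (at least 2.52-fold, detected on 1 of 2 CsA arrays) (adjusted p = 0.00074, but adjusted p = 0.268 with an estimated correlation). Of 16 cell cycle genes, 6 were lower, including Mcm2 (-0.55 ± 0.11) (adjusted p = 0.000376, but adjusted p = 0.216 with an estimated correlation). Of 13 cholesterol synthesis genes, 2 were higher, Msmo1 (0.89 ± 0.14) and Cyp51 (0.79 ± 0.14) (adjusted p = 0.00714, but adjusted p = 0.544 with an estimated correlation). The cholesterol shift was lost without replicate 1 of the arrays without CsA (0.0729) or of the CsA arrays (0.0637). Naive genes did not shift (adjusted p = 0.837), and Ppp3ca (0.02 ± 0.16), Ppp3cb (-0.29 ± 0.13), Rcan1 (-0.11 ± 0.13) and Src (0.14 ± 0.20) were not called. The count of called genes was 465 without replicate 1 of the CsA arrays, 861 without replicate 2, 646 without replicate 2 of the arrays without CsA, and 730 from these 4 arrays alone. With median scaling 507 genes were higher and 957 lower.

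At day 1, 1181 genes differed, 595 higher and 586 lower with CsA, and with median scaling 464 and 685. The epiblast genes Fgf5 (9.27-fold) and Pou3f1 (6.68-fold) and Ccno (4.49-fold) were lower, and Inhbb, an activin subunit (at least 3.05-fold), Cox6a2 (at least 2.17-fold) and Tmem80 (3.13-fold) were higher. The Cox6a2 call ended without replicate 1 of the arrays without CsA (adjusted p = 0.0612) or of the CsA arrays (0.247). Of 12 primed epiblast genes, 8 were lower (adjusted p = 7.12e-08, but adjusted p = 0.110 with an estimated correlation). Of 18 naive genes, 8 were higher, with Tbx3 at 2.45-fold and Tfcp2l1 at 2.10-fold, and 1 was lower (adjusted p = 4.17e-07, but adjusted p = 0.118 with an estimated correlation). ER stress genes were higher in 7 of 17 cases, including Ddit3 (3.08-fold) and the chaperone Hspa5 (BiP, at least 2.04-fold, detected on 1 of 2 arrays without CsA) (adjusted p = 4.16e-08, but adjusted p = 0.0811 with an estimated correlation).

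Cell cycle genes shifted down at day 1 with 2 called, Mcm2 (-0.49 ± 0.11) and Plk1 (-0.38 ± 0.12) (adjusted p = 0.000802, but adjusted p = 0.226 with an estimated correlation). Blood and endothelium genes shifted down with Tal1 called (-1.47 ± 0.18) (adjusted p = 0.0360, but adjusted p = 0.166 with an estimated correlation), and cholesterol synthesis genes shifted up with Msmo1 called (0.84 ± 0.14) (adjusted p = 0.0431, but adjusted p = 0.642 with an estimated correlation). The calls of Mcm2 and Plk1 ended without replicate 1 of the arrays without CsA (0.0958 and 0.245) or of the CsA arrays (0.137 and 0.325), and that of Plk1 without replicate 2 of the arrays without CsA (0.0617). The blood and endothelium shift was lost without a detection filter (0.0998), without replicate 1 of the arrays without CsA (0.0751) and without replicate 2 of the CsA arrays (0.185). The cholesterol shift was lost without replicate 1 of either group (0.203 and 0.204), without background correction (0.0523), with median scaling (0.0641) and from the series matrix (0.0561). Also, Ppp3ca (-0.10 ± 0.16), Ppp3cb (-0.17 ± 0.13), Rcan1 (-0.10 ± 0.13) and Src (0.00 ± 0.20) were not called. Leaving out replicate 1 or 2 of the CsA arrays gave 446 or 766 genes, and replicate 1 or 2 of the arrays without CsA 598 or 633.

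By day 3 the CsA difference was as wide as the response to LIF withdrawal, at 4183 genes, 2085 higher and 2098 lower, with 479 and 534 by at least 2-fold. Higher with CsA were Cox6a2 (at least 12.8-fold), the naive factor Tbx3 (10.7-fold), Megf11 (10.3-fold), the adhesion receptor Adgre5 (9.96-fold) and Zmym3 (8.88-fold), besides Psmc1 (by at least 3.38 on the log2 scale). Lower were Acta2 (21.4-fold), Fgf8 (at least 14.4-fold), Egr1 (at least 11.8-fold), Cbln4 (at least 11.5-fold), the blood and endothelial factor Etv2 (13.1-fold) and the muscle protein gene Pdlim3 (at least 3.48 on the log2 scale). Cox6a2, Fgf8, Egr1 and Pdlim3 were detected on 1 of 2 arrays of their dimmer group.

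Of 18 naive genes, 17 were higher with CsA at day 3 (adjusted p = 1.58e-15, and 0.0488 with an estimated correlation), including Pecam1 (7.93-fold), Klf4 (4.09-fold) and Jam2 (3.96-fold). LIF-STAT3 targets split, 4 higher and 9 lower, without a shift (adjusted p = 0.407). Ier3 (-2.56 ± 0.23) and Junb (-2.23 ± 0.21) were lower and Tfcp2l1, which the naive list shares, was higher. Of 12 primed epiblast genes, 9 were lower, including Fgf5 (8.34-fold) and Pim2 (8.23-fold) (adjusted p = 2.13e-05, but adjusted p = 0.169 with an estimated correlation). Of 15 Src family and ERK feedback genes, 10 were lower and 1 higher, with Dusp6 at -1.96 ± 0.25 and Fos at least 2.19-fold lower (adjusted p = 0.00215, but adjusted p = 0.346 with an estimated correlation). Imprinted genes were lower in 7 of 12 cases, with Igf2 (3.59-fold), Cdkn1c (3.21-fold) and Dlk1 (2.88-fold) (adjusted p = 0.00686, but adjusted p = 0.114 with an estimated correlation). Neuroectoderm genes were lower in 5 of 7 cases and higher in 1, with Nes at least 2.82-fold and Pax6 2.88-fold lower (adjusted p = 0.0342, but adjusted p = 0.165 with an estimated correlation). The neuroectoderm shift was lost without background correction (0.193), from the series matrix (0.208) and without replicate 2 of the CsA arrays (0.0557).

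ER stress genes were still higher with CsA at day 3, 8 of 17 with 1 lower, led by Ddit3 (5.80-fold) and Sdf2l1 (4.22-fold) (adjusted p = 0.00389, but adjusted p = 0.317 with an estimated correlation). Cell cycle genes were lower in 9 of 16 cases, with Ccne1 at -1.19 ± 0.16 (adjusted p = 0.0135, but adjusted p = 0.389 with an estimated correlation). Ppp3ca was higher (0.68 ± 0.16), and Ppp3cb (0.06 ± 0.13), Rcan1 (0.04 ± 0.13) and Src (0.26 ± 0.20) were not called. The second Rcan1 probe was lower with CsA (-0.93 ± 0.21, adjusted p = 0.00126 over probes), a call that ended without background correction (0.0592) and from the series matrix (0.0650). Its day 3 interaction (adjusted p = 0.0357) was lost in those settings (0.283 and 0.296), with median scaling (0.0832) and without 6 of 8 arrays in turn. The CsA differences of different days share no arrays. All 643 genes called at both day 0 and day 1 differed the same way (77.7 expected of independent lists), and of 957 called at both day 0 and day 3, 894 did (275.5 expected).

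The interaction asks directly whether the response to LIF withdrawal differed with CsA. At day 3 it was called for 1678 genes, 877 higher and 801 lower. The naive genes stood out: 17 of 18 changed in a more positive direction with CsA (adjusted p = 3.76e-21, and 0.0275 with an estimated correlation), such as Tbx3 (2.86 ± 0.24), Pecam1 (2.21 ± 0.23) and Klf4 (2.10 ± 0.24). The largest interactions were in Megf11 (3.23 ± 0.33), the meiotic kinase Aurkc (3.10 ± 0.35), Fgf8 (-4.09 ± 0.40), Acta2 (-3.95 ± 0.31) and Cbln4 (-3.70 ± 0.25), and in Psmc1 (5.78 ± 1.3), whose probe is unreliable. Each of Fgf8, Acta2, Cbln4 and Psmc1 was undetected on both arrays of 1 to 3 of the 4 groups, so these sizes depend on the background. With levels raised to each array's lowest detected level, a setting chosen after the data were seen, they were -3.91, -4.40, -3.54 and 4.97, all called. Without background correction and from the series matrix the calls of Fgf8 (adjusted p = 0.0991 and 0.119) and Acta2 (0.392 and 0.444) ended, as did that of Cbln4 from the series matrix (0.0582). Nanog also had a positive interaction (1.12 ± 0.15), and none was called for Ppp3ca (0.66 ± 0.23, adjusted p = 0.0568), Ppp3cb (0.36 ± 0.19), Rcan1 (0.15 ± 0.19) and Src (0.12 ± 0.29).

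Several lists had an interaction at day 3 that was lost with an estimated correlation. Of 13 epithelial genes, 4 were more negative and 1 more positive, with Cldn7 at -2.26 ± 0.33, or -1.87 with levels so raised (adjusted p = 0.00193, but adjusted p = 0.146 with an estimated correlation). Of 15 Src family and ERK feedback genes, 5 were more negative, led by Egr1 (-2.44 ± 0.37, or -2.09 with levels so raised) (adjusted p = 0.00171, but adjusted p = 0.344 with an estimated correlation). For imprinted genes 5 of 12 were more negative (adjusted p = 0.00756, but adjusted p = 0.114 with an estimated correlation), for primed epiblast genes 4 of 12 (adjusted p = 0.0091, but adjusted p = 0.404 with an estimated correlation), and for fibroblast genes 2 of 7 (adjusted p = 0.0431, but adjusted p = 0.179 with an estimated correlation). The primed epiblast shift was lost without background correction (0.115), from the series matrix (0.136) and without replicate 1 of day 3 with CsA (0.0650). The fibroblast shift was lost without background correction (0.313), from the series matrix (0.324), with median scaling (0.0527), with the mean of probes (0.0669) and from its own series (0.0513). It was also lost without replicate 1 of day 0 (0.0938) or replicate 2 of day 3 (0.0630) without CsA, and without replicate 1 of day 0 (0.109) or replicate 2 of day 3 (0.101) with CsA. LIF-STAT3 targets had no interaction as a list (adjusted p = 0.896). Without replicate 1 of day 3 with CsA the interaction count was 998.

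Of the 4192 genes that changed at day 3 without CsA, 1317 had an interaction, and for 1277 of them, 96.96%, the change was smaller with CsA or turned. That covers 620 risen and 657 fallen genes, against 23 and 17 with a larger change. The comparisons share arrays, which alone gives r = -0.71 across genes in simulated unchanged groups (observed r = -0.69, covariance -0.281 against -0.0343 simulated). Part of the 1317, against 640.6 expected of independent lists, may come from the shared arrays. So may the 96.96%, since the interaction subtracts the change without CsA. No simulated share was computed, so the 96.96% alone does not show a smaller response. Without replicate 1 of day 3 with CsA the 1317 became 874. The courses with and without CsA share no arrays. Of the 4192 genes, 1908 were called the same way in the course with CsA, 115 the opposite way and 2169 not (r = 0.65 across genes). The day 3 response with CsA had a slope of 0.63 on that without, over 845 genes with a mean change of at least 1 on the log2 scale, and single replicates gave 0.60 to 0.66.

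At day 1 the interaction was called for 8 genes, 2 higher and 6 lower, with 625 at an unadjusted p under 0.05. Interactions were negative for Fgf5 (-3.16 ± 0.35), Gbp2b (-1.89 ± 0.32), Vrtn (-1.79 ± 0.33) and Dcn (-1.76 ± 0.25), and positive for Tfcp2l1 (1.03 ± 0.18), which fell less, and the dicarboxylate transporter Slc13a2 (1.42 ± 0.26). All but Tfcp2l1 were undetected on both arrays of 1 to 3 of the 4 groups, so these sizes depend on the background. With levels raised to each array's lowest detected level, Fgf5 was at -3.23, Vrtn at -1.81, Dcn at -1.41 and Slc13a2 at 1.11, and the call of Gbp2b ended (adjusted p = 0.0664). No interaction was called at day 1 for Ppp3ca (-0.12 ± 0.23), Ppp3cb (0.12 ± 0.19), Rcan1 (0.01 ± 0.19) and Src (-0.15 ± 0.29). Positive shifts were called for naive genes (adjusted p = 1.29e-09, but adjusted p = 0.0801 with an estimated correlation) and LIF-STAT3 targets (adjusted p = 1.23e-06, but adjusted p = 0.0774 with an estimated correlation). A negative shift was called for primed epiblast genes (adjusted p = 0.00633, but adjusted p = 0.367 with an estimated correlation). The primed epiblast shift was lost without background correction (0.353), from the series matrix (0.4) and without replicate 1 of day 1 without CsA (0.151). The gene count was 0 in limma without background correction or from the series matrix (615 and 619 at an unadjusted p under 0.05), 1 with the mean of probes, 3 without a detection filter, 4 from its own series and 5 from the arrays compared. Without replicates 1 and 2 it was 2 and 4 for day 0 without CsA, 3 and 2 for day 0 with CsA, and 2 and 4 for day 1 with CsA, and without replicate 1 of day 1 without CsA it was 5. The calls of Fgf5 and Dcn stood with any array left out, and those of Gbp2b, Vrtn, Tfcp2l1 and Slc13a2 ended without 6, 7, 6 and 7 of the 8 arrays in turn (adjusted p up to 0.149, 0.258, 0.112 and 0.217).

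After 1 day of deltaCnA induction, 1226 genes had changed, 718 up and 508 down. No cells without the transgene were put through Tc withdrawal among these samples. Effects of deltaCnA are therefore not separated from those of Tc removal, fresh medium or handling. The lipoxygenase gene Alox12e (at least 3.62-fold), the transporter gene Abca14 (5.16-fold) and cyclin D2, Ccnd2 (4.15-fold) rose most. The lipoprotein receptor gene Vldlr fell at least 4.66-fold, to a level detected on 1 of 2 arrays. Ubap1l (-2.73 ± 0.47) and the stress gene Nupr1 (-2.46 ± 0.45) fell too, with wide spreads at day 1 (log2 level 6.81 ± 1.67 and 8.84 ± 1.78, SD, n = 2). Of 17 ER stress and integrated stress response genes, 8 fell, with Chac1 (4.49-fold), Ddit3 (4.14-fold) and Cebpb (2.62-fold), although Chac1 too had a wide spread at day 1 (9.03 ± 1.76, SD, n = 2) (adjusted p = 4.02e-05, but adjusted p = 0.163 with an estimated correlation). Of 13 p53 targets, 7 fell, with Pmaip1 (Noxa) at least 2.12-fold and Cdkn1a (p21) 1.66-fold lower, although the Cdkn1a call ended without replicate 2 of day 0 (adjusted p = 0.0569) or replicate 1 of day 1 (0.0605) (adjusted p = 5.84e-06, but adjusted p = 0.114 with an estimated correlation).

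Of 13 cholesterol synthesis genes, 6 rose after 1 day of deltaCnA, including Srebf2 (0.61 ± 0.14), whose call ended without replicate 2 of day 0 (adjusted p = 0.129) or replicate 1 of day 1 (0.144) (list adjusted p = 0.000212, but adjusted p = 0.432 with an estimated correlation). Naive pluripotency (adjusted p = 0.216), core pluripotency (0.468) and LIF-STAT3 targets (0.719) did not shift, while Gbx2 rose (1.19 ± 0.17). Ppp3ca (-0.18 ± 0.16), Ppp3cb (-0.34 ± 0.13) and Src (-0.02 ± 0.20) were not called, and Ppp3cc fell (-0.87 ± 0.22), a call that ended without replicate 2 of day 0 (0.148) or replicate 1 of day 1 (0.203). The array probes may lie outside the part of calcineurin A that the transgene carries, so the calcineurin values do not check its induction. Rcan1, a known NFAT target, was not called by its brightest probe (-0.20 ± 0.13), by the second (0.62 ± 0.21, adjusted p = 0.0691, undetected on both arrays of day 0) or by the third (-0.25 ± 0.18). The count of changed genes was 239 without replicate 1 of day 1, 332 without replicate 2 of day 0 and 696 without replicate 1 of day 0.

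After 4 days of deltaCnA, 376 genes had changed, 291 up and 85 down, of which 81 and 19 by at least 2-fold. Igf2 (6.74-fold), the homeobox gene Nkx6-3 (5.14-fold), the collagen IV genes Col4a1 (5.12-fold) and Col4a2 (4.90-fold), Abca14 (5.03-fold) and the keratin gene Krt23 (at least 3.55-fold) rose most. The neural regulator Pax6 (3.13-fold), Cbr3 (3.05-fold), Zscan5b (2.69-fold), Sall3 (2.43-fold) and the Nodal targets Lefty2 (2.41-fold) and Lefty1 (2.32-fold) fell most. The calls of Lefty2 and Lefty1 ended without replicate 1 (adjusted p = 0.0816 and 0.113) or 2 (0.125 and 0.154) of day 0 and without replicate 1 (0.138 and 0.224) or 2 (0.0862 and 0.0841) of day 4, and that of Krt23 from the series matrix (0.0526). Igf2 (1.76 ± 0.23), Col4a1 (0.91 ± 0.21) and Col4a2 (0.74 ± 0.17) had already risen at day 1. Lefty2 (-1.75 ± 0.29) and Lefty1 (-1.25 ± 0.3) had already fallen then, with SDs of 0.69 and 0.91 at day 1. At day 4 primitive endoderm genes shifted up, although of 16 only Col4a1 and Col4a2, basement membrane collagens, had risen (adjusted p = 0.000691, but adjusted p = 0.0801 with an estimated correlation). Of 7 neuroectoderm genes, 2 fell, Pax6 and Zic2 (-1.21 ± 0.22) (adjusted p = 0.0120, but adjusted p = 0.114 with an estimated correlation). Of 12 primed epiblast genes, Zic2 and Otx2 fell (adjusted p = 0.0429, but adjusted p = 0.511 with an estimated correlation). Hypoxia and glycolysis genes shifted up with Pfkp called (0.67 ± 0.12) (adjusted p = 0.00756, but adjusted p = 0.333 with an estimated correlation).

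Some of these day 4 calls ended with an array left out. Without replicate 2 of day 0 or replicate 1 of day 4 they were those of Zic2 (adjusted p = 0.0913 and 0.0507), Otx2 (0.186 and 0.111) and the hypoxia list (0.184 and 0.0803), and without replicate 1 of day 4 also that of Pfkp (0.0727). The primed epiblast shift was lost without replicates 1 and 2 of day 0 (0.0581 and 0.0582), replicate 2 of day 4 (0.126) or a detection filter (0.0581). The hypoxia shift was lost with the mean of probes (0.215) or median scaling (0.0520), and the neuroectoderm shift from its own series (0.0513).

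Of 18 naive genes, 0 were called in limma at day 4 of deltaCnA, with 3 at an unadjusted p under 0.05 (adjusted p = 0.0555 for the list, median 0.21), with Klf4 at 0.40 ± 0.17 and Jam2 at 0.47 ± 0.17. Of 17 ER stress genes, 0 were called, with 3 at an unadjusted p under 0.05 (adjusted p = 0.592 for the list), with Ddit3 at 0.46 ± 0.20. Lists of mesendoderm (adjusted p = 0.143), mesoderm (0.621), trophectoderm (0.979), fibroblast (0.622), epithelial (0.753) and calcineurin-NFAT genes (0.724) did not shift. Ppp3ca (-0.25 ± 0.16), Ppp3cb (-0.11 ± 0.13), Rcan1 (-0.11 ± 0.13) and Src (-0.11 ± 0.20) were not called. The count of changed genes was 230 and 133 without replicates 1 and 2 of day 0, 108 and 195 without those of day 4, and 684 from the 4 arrays of these groups alone.

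**Figure D3:**
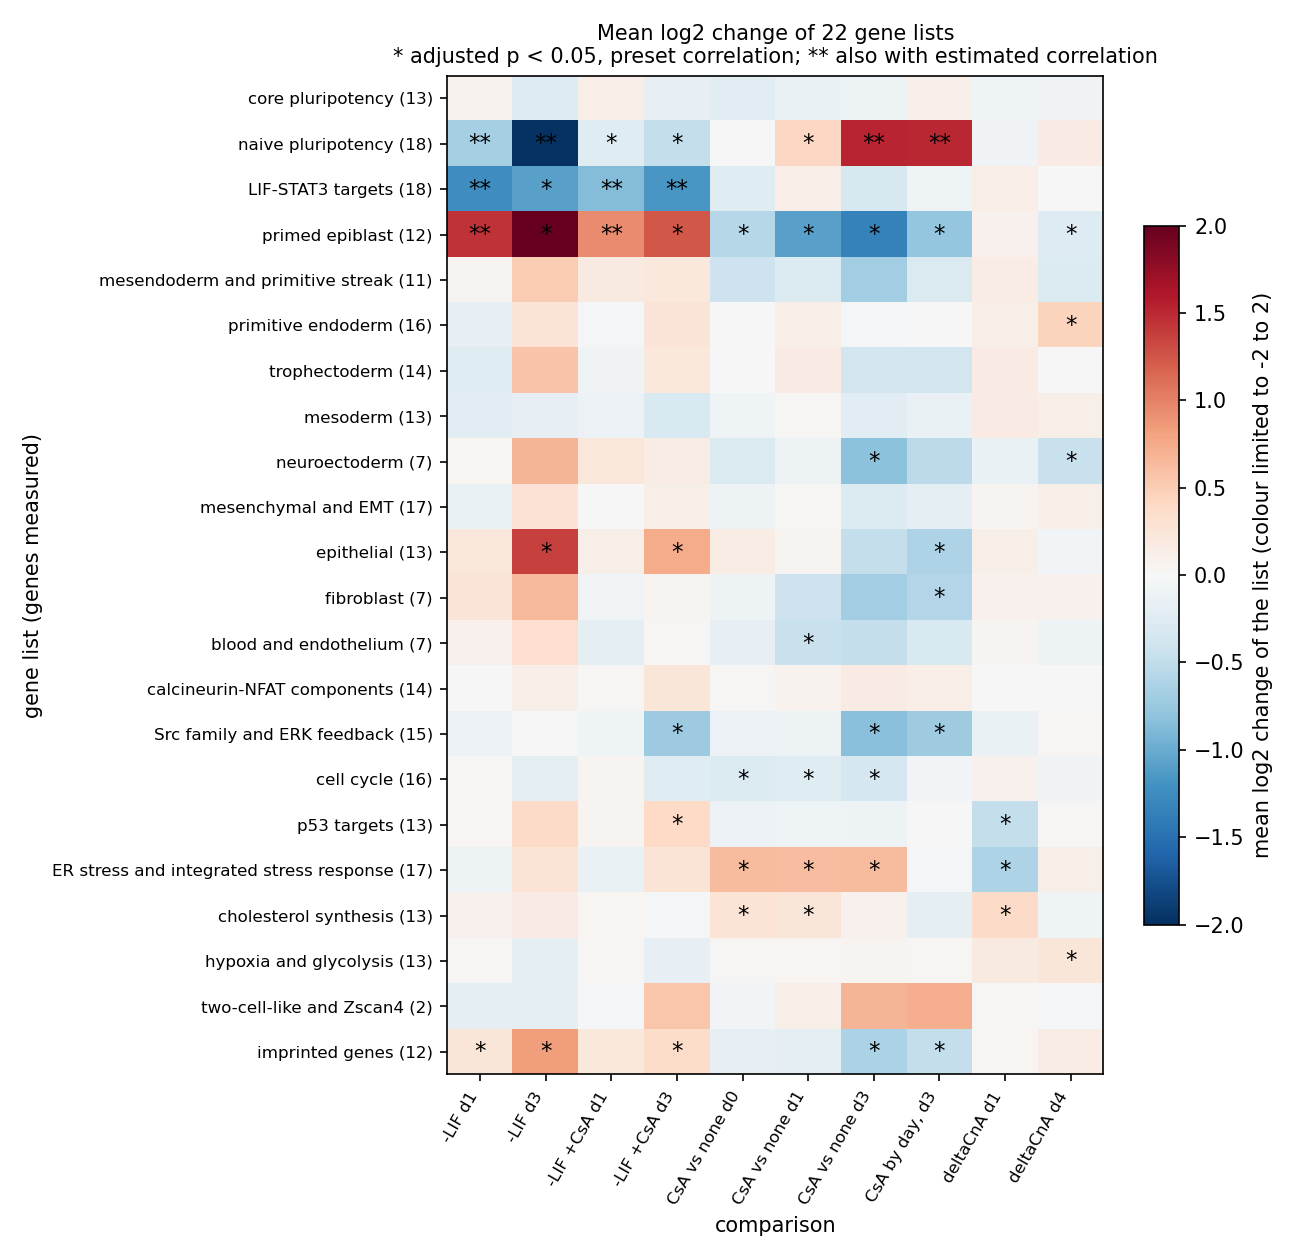
Mean log2 change of each gene list (vertical axis, with the number of genes measured) in 10 comparisons (horizontal axis), with red for higher, a single star for an adjusted p under 0.05 at the preset correlation and a double star where an estimated one also passed. Naive pluripotency is lowest at day 3 without LIF (mean -1.98) and higher with CsA at that day (mean 1.52).

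Gene calls with deltaCnA were also set beside those of LIF withdrawal and CsA. The labels do not say whether LIF was present during deltaCnA induction. Of 261 genes called in both deltaCnA at day 4 and LIF withdrawal at day 3, which share no arrays, 97 moved the same way, against 70.4 expected of independent lists, and 164 moved in opposite ways, against 73.2. Both rose for 68 genes (53.5 expected, Fisher's exact test p = 0.0315), and 135 fell without LIF but rose with deltaCnA (57.6 expected, Fisher's exact test p = 3.87e-25). Across all 10980 genes the changes barely correlated (r = -0.07), and same-way and opposite counts both exceeded expectation. The counts therefore describe the called genes only. The same-way count was 54 and 37 without replicates 1 and 2 of deltaCnA day 0, 32 and 42 without those of day 4, 54 without a detection filter and 170 from only the arrays compared. The opposite count was 113 and 56 without replicates 1 and 2 of deltaCnA day 0, 45 and 102 without those of day 4, and 255 from only the arrays compared, and it exceeded the same-way count in every setting. The 135 genes were 95 and 44, and 38 and 85, without the same 4 arrays.

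Of 227 genes called in both deltaCnA at day 4 and CsA at day 3, 92 moved in opposite ways (71.7 expected) and 135 the same way (71.5 expected), 108 of them higher in both (55.3 expected, Fisher's exact test p = 1.97e-13). Across all genes these changes barely correlated either (r = 0.09), and both directions exceeded expectation. The opposite count was 48 and 34 without replicates 1 and 2 of deltaCnA day 0, 30 and 47 without those of day 4, 60 without a detection filter and 146 from only the arrays compared. The same-way count was 90 and 48, and 37 and 72, without the same 4 arrays, 87 without a detection filter and 256 from only the arrays compared, and it exceeded the opposite count in every setting. The 108 genes were 77 and 40, and 32 and 60, without those arrays. Fisher's tests here treat genes as independent, which they are not, and are two-sided. Of 217 genes called in both deltaCnA and CsA at day 1, 146 moved in opposite ways (65.9 expected) and 71 the same way (66.0 expected). Leaving out an array gave 44 to 132 opposite and 20 to 76 the same way, and without a detection filter 71 and 44. The difference between the days was not tested. Within the deltaCnA series, 148 of 153 genes called at both days moved the same way, and the shared day 0 arrays alone give r = 0.50 (observed r = 0.32, covariance 0.0301 against 0.0174 simulated).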

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

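All tests of explanations in this part were chosen after the results were seen, except the test of a single day 1 array in the deltaCnA series. A direct test called a difference with CsA in the response to LIF withdrawal for 8 genes at day 1 and 1678 genes at day 3. The day 1 count was 0 in limma without background correction and from the series matrix (615 and 619 genes at an unadjusted p under 0.05). As lists, the response differed at day 1 for naive pluripotency (adjusted p = 1.29e-09), LIF-STAT3 targets (1.23e-06) and primed epiblast genes (0.00633), all lost with an estimated correlation (0.0801, 0.0774 and 0.367). At day 3 it differed for naive pluripotency (3.76e-21, and 0.0275 with an estimated correlation). At day 3 primed epiblast (0.0091), epithelial (0.00193), fibroblast (0.0431), Src family and ERK feedback (0.00171) and imprinted genes (0.00756) were called as well but lost with an estimated correlation (0.404, 0.146, 0.179, 0.344 and 0.114). Probes with no gene name, which entered no comparison, also held signal: 1486 were called at day 3 of LIF withdrawal, 1442 for CsA at day 3 and 99 at day 4 of deltaCnA.

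The ratio of the mean response with CsA to that without differed between gene lists. Over the 845 genes with a mean change of at least 1 on the log2 scale, the day 3 response with CsA had a slope of 0.63 on that without. These are not all strongly changed genes, since 1339 were called at 2-fold or more at day 3 of LIF withdrawal without CsA. Of the 6 lists with a usable ratio, among those called in either course, 4 had a range over single replicates apart from that of the slope. The ratio of mean changes was 0.24 for naive pluripotency (0.22 to 0.26), 1.08 for LIF-STAT3 targets (1.00 to 1.16), 1.02 for p53 targets (0.89 to 1.2) and 0.44 for imprinted genes (0.38 to 0.53), while primed epiblast (0.62) and epithelial genes (0.55) lay near the slope. The 1.08 of the LIF-STAT3 targets averages opposite effects, since limma called interactions for 8 of 18, 4 positive such as Klf4 (2.10 ± 0.24) and 4 negative such as Ier3 (-2.63 ± 0.33), and the p53 targets counted only by their call with CsA. The Src and ERK list has no usable ratio, since its mean change without CsA was -0.01. The ranges hold the spread between arrays, not that between the genes of a list. They therefore cannot decide whether 1 factor with scatter between genes would give such ratios, and what sets the lists apart stays open.

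CsA arrays differed from the others at day 0, where no LIF had been withdrawn by the labels' count of days. An earlier withdrawal of LIF from those cells would lower the STAT3 targets, which had fallen by a median of 0.90 after 1 day without LIF. Their median difference at day 0 was -0.21, which argues against it. Still, of 18 such targets 3 were called lower with CsA and 0 higher. They were Junb (-0.76 ± 0.21), Pim1 (-0.64 ± 0.19) and Cish (-0.55 ± 0.15), and camera called no shift of the list (adjusted p = 0.12). Chance differences of these 4 arrays would not return on others, yet 95.99% of the genes differed the same way at day 1 and 84.99% at day 3. A batch shared by the CsA groups and an effect of CsA itself cannot be told apart, since both could give the correlation of 0.66 between the differences at day 0 and day 1.

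More genes changed after 1 day of deltaCnA than after 4 days. Day 0 arrays that stood apart are argued against by the 1721 genes called between day 1 and day 4. A single aberrant day 1 array would not be shared: of 1099 genes called with replicate 1 of day 1 alone, 84.26% differed the same way between replicate 2 and day 4, but without replicate 1 the day 1 count was 239, near the 108 to 230 of day 4 without an array, so whether the larger count rests on that array stays open. Scaling is argued against by the lowest day 1 count under other background and scaling settings, 1087, above the highest day 4 count of 394. A transient effect of deltaCnA may be involved, but removal of Tc, fresh medium or handling at day 1 stays open, as no cells without the transgene were put through Tc withdrawal among these samples.

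Within groups, replicates of Fbxw5 differed by up to 4.83 and those of Psmc1 by up to 4.17 on the log2 scale, so calls of these genes rest on probes that read on some arrays only.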

How the results depend on the processing

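Chosen after the data were seen were the settings with unnamed probes, with only the arrays of a gene's own series, with a replicate block per series, without the unreliable probes of Fbxw5 and Psmc1, and, for named interactions, with levels raised to the lowest detected one. LIF withdrawal at day 3 and CsA at day 3 stayed within 1.5 times of 4192 and 4183 genes under all settings, with 3177 to 3787 and 2900 to 3805 when an array was left out. The slope ran from 0.62 to 0.65 in all settings.

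The labels do not say that equal replicate numbers mark a shared culture or day, and each comparison has only 2 pairs. Same-numbered arrays deviated together within LIF and CsA groups (r = 0.05 to 0.35 over 15 pairs) and deltaCnA groups (0.13 to 0.20), not between them (-0.21 to 0.06). Within their own series all 18 arrays correlated best with one of their own number. The 2 arrays of a group deviate as mirror images, so they do not count separately. The planned replicate block gave 4353 genes for LIF withdrawal at day 3, 4352 for CsA at day 3 and 442 for deltaCnA at day 4, and no count moved by over 1.5 times. A replicate block per series gave 827 genes for LIF withdrawal with CsA at day 1, 2277 and 1959 for CsA at days 0 and 1, 24 for the day 1 interaction, 2033 and 780 for deltaCnA at days 1 and 4, and 219 and 194 for the same-way and opposite overlaps, whose counterparts became 326 and 301. It also ended 2 of 52 list shifts, neuroectoderm for CsA at day 3 (adjusted p = 0.0526) and fibroblast for the day 3 interaction (0.0612). The BeadChip block was not run, as the files name no chip.

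From only the arrays compared, CsA at day 0 gave 730 genes, deltaCnA at day 4 684, the day 1 interaction 5, and the overlaps 170 and 146. Without a detection filter the interaction gave 3 and the overlaps 54 and 60, and there Nfatc1 at day 3 of LIF withdrawal (-0.03) and Sox7 at day 1 of deltaCnA (-0.02) reversed, of which the cause was not tested. The day 1 interaction gave 0 without background correction, 0 from the series matrix, 1 with the mean of probes and 4 from its own series. Gene list shifts fell from 52 to 9 with an estimated correlation.

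Leaving out an array, with its partner assumed to vary like the other groups, gave 476 to 727 genes for LIF withdrawal at day 1, 236 to 294 and 2032 to 2781 with CsA at days 1 and 3, 465 to 1065 and 446 to 766 for CsA at days 0 and 1, 2 to 8 and 998 to 1804 for the interactions, 239 to 1099 and 108 to 230 for deltaCnA at days 1 and 4, 874 to 1362 for genes whose LIF response differed with CsA, and 32 to 94 and 30 to 93 for the overlaps. Of 574 named gene values, 339 kept their call in all settings, 133 lost it in some setting other than leaving out an array and 205 without some array. Of 52 list shifts, 10 lost their call without some array.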

Other observations

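The gene lists in this part were drawn up after the largest changes had been seen, and each was tested without the genes that prompted it, over 55 tests (5 lists in 11 comparisons). The other settings and the leaving out of arrays were not run on these lists. Interferon and antigen processing genes rose by day 3 of LIF withdrawal, 12 of 19 with 2 lower (adjusted p = 6.02e-05, and 0.0069 with an estimated correlation). They included the tetherin gene Bst2 (2.34 ± 0.16), the proteasome genes Psmb9 (1.70 ± 0.17) and Psme1 (1.63 ± 0.12), and B2m (1.46 ± 0.16), the light chain of MHC class I, while Irf9 (-1.63 ± 0.17) and Stat2 (-0.86 ± 0.18) fell. With CsA at day 3, 13 of the 19 were lower and 2 higher (adjusted p = 2.73e-05, and 0.00592 with an estimated correlation), and the interaction was called for 10 (adjusted p = 1.55e-05). Actin cytoskeleton genes and targets of SRF, the factor that drives them, rose with LIF withdrawal too, 13 of 19 with 1 lower (adjusted p = 8.18e-08, and 0.00284 with an estimated correlation), among them Ccn1 (2.91 ± 0.21), Cnn2 (2.00 ± 0.19) and Srf itself (1.45 ± 0.13). With CsA at day 3, 15 of 19 were lower (adjusted p = 8.65e-10, and 0.00161 with an estimated correlation), including Tpm1 (-2.80 ± 0.13). At day 1 of LIF withdrawal this list had shifted up with CsA present (adjusted p = 0.00878, and 0.0453 with an estimated correlation). Without CsA it had shifted up at day 1 too (adjusted p = 0.0351, but adjusted p = 0.0856 with an estimated correlation).

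Genes for ER chaperones and ER-associated degradation were higher with CsA before and after LIF withdrawal, 14 of 16 at day 0 (adjusted p = 7.26e-15, and 0.00592 with an estimated correlation), 13 at day 1 and 15 at day 3. At day 0, Pdia6 (1.18 ± 0.20), Selenos (1.12 ± 0.16) and Hyou1 (1.01 ± 0.18) were among them. The interaction at day 3 was not called (adjusted p = 0.503). With deltaCnA at day 1 the list shifted up as well (adjusted p = 0.00364, but adjusted p = 0.201 with an estimated correlation), with P4hb (0.50 ± 0.12) and Sel1l (0.46 ± 0.14) risen.

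Whether calcineurin, other targets of CsA such as the cyclophilins of the ER, or a batch shared by the CsA groups gave the ER shift (7.26e-15 at day 0) is open. With deltaCnA at day 1, the mixed list of ER stress and integrated stress response genes shifted down while ER chaperones shifted up. Neither was called with an estimated correlation (adjusted p = 0.163 and 0.201). The fall of the mixed list at the preset correlation was not seen in the chaperone list, where 2 of 16 genes were called higher and 0 lower. At day 4 limma called 0 of 16 chaperone genes (adjusted p = 0.45 for the list). For actin and interferon genes the interaction at day 3 was called also with an estimated correlation (adjusted p = 0.00161 and 0.00592), and the lists were not called at day 0 (adjusted p = 0.0662 and 0.297). Single members already differed with CsA at day 0, 3 of 19 lower and 1 higher on each list. Tpm1 (-0.68 ± 0.13) and Psmb9 (-1.17 ± 0.17) were among the lower ones.

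Amino acid response genes, targets of ATF4, fell at day 1 of deltaCnA, 12 of 17 (median -0.66, adjusted p = 3.77e-11), but adjusted p = 0.0856 with an estimated correlation leaves open whether they fell as a group. They included the tRNA synthetases Iars (-1.34 ± 0.23) and Nars (-0.90 ± 0.17) and the serine and folate enzymes Shmt2 (-0.89 ± 0.17) and Mthfd2 (-0.82 ± 0.18), and at day 4 limma called 0 of 17, with 1 at an unadjusted p under 0.05. Fresh medium at the removal of Tc could give such a change, and no arm among these samples tests it. The basement membrane list, tested without Col4a1 and Col4a2, shifted up at day 4 of deltaCnA (adjusted p = 0.0314, but adjusted p = 0.176 with an estimated correlation). Of its 16 genes, 3 rose, the integrin Itga3 (0.77 ± 0.21) and the collagen-processing genes P4ha2 (0.69 ± 0.19) and Serpinh1 (0.56 ± 0.16). The laminin genes of the list were among the 13 not called.

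Before induction, the deltaCnA cells differed from the cells at day 0 of LIF withdrawal at 1911 genes, 730 higher and 1181 lower in the deltaCnA cells. Clone, transgene, culture conditions and array batch are not separated there.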
